A study of Synechococcus elongatus PCC 7942 = FACHB-805 with 10 samples.

How the data were processed

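RNA-seq was measured in 10 libraries of the cyanobacterium Synechococcus elongatus PCC 7942, in 5 groups of 2 libraries with the letters A and B. The control was day 0, and the stressed cultures were sampled on day 1 and day 3 of 0.4 M NaCl or of 50 mg/L streptomycin. Per the labels' protocols, cells grew at 30 °C in BG11 medium under continuous light of 70 µE m-2 s-1, and total RNA was taken with TRIzol LS. The labels do not say whether the letters mark separate cultures or a shared day, so the p-values measure only the spread between these samples, which may be technical.

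Per the file headers, the deposited tables gave raw counts per coding sequence, RPKM and TPM for 2661 genes, 1 table for the A libraries and 1 for the B libraries. The deposited RPKM equalled count over coding length and column total to within 6e-10 of the recomputed value, and the deposited TPM summed to 100% of its nominal total in each library. The RPKM and TPM were used only in these checks. Bowtie is named in the submitters' processing notes; its version, the counting tool, the genome build and the use of strand are not given in the sources used here. Every gene in the tables was a coding sequence, so library sizes hold no ribosomal or transfer RNA. In the B table the locus tag column disagreed with the gene ID on 49 genes of the B-prefixed tags. The tables were therefore joined by gene ID, which gave Spearman correlations of 0.956 to 0.989 between A and B over those genes, against -0.139 to -0.006 when joined by the locus tag column. Genes were named by locus tag with the product text of the tables. None of the locus tags matched the reference gene table (0 matched), so no symbols or coordinates were taken from it, and no genome was used.

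Total counts were between 2784332 and 8417282 per library, and a floor of 3 counts corresponded to 0.356 to 1.08 CPM of these totals, without the TMM scaling used for levels. Intervals and floors of this kind cover counting error only. Replicates of a group had Spearman correlations of 0.981 to 0.994 across genes and differed beyond sampling noise, with chi-square per degree of freedom of 22.0 to 101, so all were kept as separate libraries.

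Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM factors, filterByExpr on the 5 groups, a group means model over all 10 libraries with 5 residual degrees of freedom, and the robust quasi-likelihood F test. The filter left 2654 genes and removed 7. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, a gene was called at an adjusted p under 0.05, and each SE is the size of the log2 fold change over the square root of F. Levels are TMM-scaled CPM, as mean ± SD of 2 libraries. The comparisons were each stress and day against the control, day 3 against day 1 within each stress, streptomycin against NaCl on each day, and the difference of the day 1 to day 3 change between the stresses.

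Lists of genes by function were fixed as word patterns, with the tests and comparisons, before the data were examined, and 33 of 34 lists had members, covering 619 genes. The wording was then extended and corrected after the product texts had been read and before any fold change was computed. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, again with the correlation estimated per list, and with fry, adjusting over the 33 lists within each comparison. Camera compares a list with all other genes.

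The genes named follow a rule fixed at the same time. For each comparison with the control it takes the 8 largest changes each way among called genes with a protein symbol, moving the same way in A and B and with at least 20 CPM in the higher group, the 2 largest each way without a symbol, and up to 3 members each way of each list, or all members of lists of up to 8. For the other comparisons it takes 5 and 2 each way. The tables give no gene symbols, so a protein symbol in the product text stood in for one (253 genes). That substitution was made after the files had been read.

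The overlap of the NaCl and streptomycin responses was set beside 30 simulated data sets in which every group, the control included, was unchanged. On counts simulated for NaCl day 1 against control over 2647 genes, the same steps called 90 of 100 genes changed 2-fold and 99 of 100 changed 4-fold, and 19 unchanged genes. These were 9.13% of the calls, above the nominal level. Only 200 genes were changed in that simulation, while 63.5% of the genes tested were called on NaCl day 1 in the data. The simulated share therefore does not carry over to the called counts, whose share of false calls is not known.

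The alternatives tried were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library size alone, other filters on low counts, only the libraries compared, the letter as a block, and leaving out each library in turn. Camera with library size alone and the lists as first worded were added after seeing the data. Figures were drawn with matplotlib 3.10.9.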

Results

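Messenger RNA levels were measured in Synechococcus elongatus PCC 7942, a freshwater cyanobacterium, before stress (control, day 0) and on day 1 and day 3 of 0.4 M NaCl or of 50 mg/L streptomycin, an antibiotic that inhibits protein synthesis. Each of the 5 groups held 2 libraries. Total counts were 4386954 and 8417282 in the control, 4456000 and 8364833 on NaCl day 1, 2784332 and 4298458 on NaCl day 3, 6354352 and 6934283 on streptomycin day 1, and 2989758 and 4338936 on streptomycin day 3. The control libraries gave 16.1% and 15.4% of their counts to 1 hypothetical protein gene, Synpcc7942_0905. The metal-binding protein SmtA metallothionein (Synpcc7942_1290) took the most counts in all 6 libraries of NaCl day 3 and of both streptomycin days, between 7.20% and 15.6%. Every control library was from day 0, so each comparison with the control holds the stress and the time in culture together. Below, changes are log2 fold changes ± SE from edgeR with n = 2 libraries per group, levels are CPM as mean ± SD, and a gene is said to rise or fall only where its adjusted p was under 0.05.

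The direction of small changes depended on the scaling. TMM factors were 0.573 and 0.659 in the control, against 1.70 and 1.74 on NaCl day 1 and 1.30 and 1.46 on NaCl day 3. With library size alone, the median gene moved up by 1.50 on NaCl day 1, 1.15 on NaCl day 3, 0.50 on streptomycin day 1 and 0.39 on streptomycin day 3 against the control (upper-quartile factors gave 0.23, 0.21, 0.38 and 0.30). The median was -1.0 between streptomycin and NaCl on day 1 and -0.75 on day 3, -0.34 from NaCl day 1 to day 3, and 0.26 for the difference of the time changes. Changes below are relative to the TMM scale, on which all of these medians were between -0.03 and 0.03. Camera called 49 lists over the 9 comparisons, of which 0 were called with an estimated correlation, where adjusted p was 0.257 to 0.803 and 14 had an unadjusted p under 0.05. By fry, which asks whether a list's own genes move one way, 48 of the 49 were called in the same direction, all but ATP synthase from streptomycin day 1 to day 3 (adjusted p = 0.0560). These lists had been picked by camera for a shift in the same data, so the fry result is not separate support for them.

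On day 1 of NaCl, transcripts of a bicarbonate transporter, of some genes with nitrate transport in their product text and of the type IV pili list were lower than in the control. Among the genes named, the largest fall was that of the sodium-dependent bicarbonate transporter (Synpcc7942_1475), from 11340 ± 1067 CPM to 15.99 ± 4.47 CPM (-9.45 ± 0.53, adjusted p = 3.65e-08). Next to it in size were a membrane protein (Synpcc7942_1488, -9.31 ± 0.58), a nitrate transport permease (Synpcc7942_1489, -7.80 ± 0.54) and nitrate transport ATP-binding subunits C and D (Synpcc7942_1490, -7.21 ± 0.51). The largest rise among them was that of a Beta-Ig-H3/fasciclin protein (Synpcc7942_1606, 7.52 ± 0.35, adjusted p = 1.16e-08), followed by a hypothetical protein (Synpcc7942_0374, 4.89 ± 0.28). In all, 1684 of 2654 genes changed, 843 higher and 841 lower, and 1090 changed at least 2-fold; with library size alone the split was 2000 higher and 241 lower.

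Of the photosystem I list on NaCl day 1, 9 of 12 measured members fell, 2 rose and 1 did not pass the test, and the median of -1.47 went to 0.0 with library size alone. Of them, 9 were lower and 2 higher when adjusted over the list alone. Camera p was 0.0049, with adjusted p = 0.0404, and adjusted p = 0.508 with an estimated correlation. The core proteins PsaB (Synpcc7942_2048, -3.57 ± 0.21) and PsaA (Synpcc7942_2049, -3.40 ± 0.22), which bind the reaction centre pigments, and subunit IX (Synpcc7942_1249, -3.02 ± 0.20) fell. Of the phycobilisome list, the light-harvesting antenna, 11 of 15 measured members fell, 1 rose and 3 did not pass the test. The median was -1.55 (-0.09 with library size alone), and 11 were lower and 1 higher when adjusted over the list alone. Camera p was 0.00179, with adjusted p = 0.0295, and adjusted p = 0.58 with an estimated correlation. Its rod linker polypeptides Synpcc7942_1050 (-2.34 ± 0.25) and Synpcc7942_1049 (-2.20 ± 0.27) were among those that fell. Of the NDH-1 list, 12 of 17 measured members fell, 2 rose and 3 did not pass the test, and the median of -0.93 went to 0.55 with library size alone. Of them, 13 were lower and 3 higher when adjusted over the list alone. Camera p was 0.00449, with adjusted p = 0.0404, and adjusted p = 0.518 with an estimated correlation. The small subunit of RuBisCO (Synpcc7942_1427), the enzyme that fixes CO2, fell by 3.91 on the log2 scale (SE 0.43).

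Of the type IV pili and competence list on NaCl day 1, 12 of 16 measured members fell, 2 rose and 2 did not pass the test. The median was -2.27 (-0.81 with library size alone), and 12 were lower and 2 higher when adjusted over the list alone. Camera p was 0.000457, with adjusted p = 0.0151, and adjusted p = 0.508 with an estimated correlation. The pilin polypeptide PilA-like gene (Synpcc7942_0049, -4.55 ± 0.25) was in it. With neighbouring locus tags, the CheY-like receivers Synpcc7942_0855 (-4.40 ± 0.29) and Synpcc7942_0856 (-4.71 ± 0.27), CheW (Synpcc7942_0857, -4.52 ± 0.18) and the CheA histidine kinase (Synpcc7942_0859, -3.64 ± 0.22) fell. Heat shock protein DnaJ-like (Synpcc7942_2306, -4.93 ± 0.19), the sigma factor SigF (Synpcc7942_1510, -4.11 ± 0.29), methyltransferase GidB (Synpcc7942_0267, -4.03 ± 0.22) and cytochrome c oxidase subunit III (Synpcc7942_2604, -2.62 ± 0.21) also fell. Of the ribosomal protein list, 26 of 53 measured members fell, 6 rose and 21 did not pass the test, and the median of -0.77 went to 0.73 with library size alone. Of them, 26 were lower and 6 higher when adjusted over the list alone. Camera p was 0.00735, with adjusted p = 0.0485, and adjusted p = 0.616 with an estimated correlation.

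Genes that rose on NaCl day 1 included a secretion protein HlyD (Synpcc7942_1870, 4.23 ± 0.24) and a probable cation efflux system protein with the adjacent tag (Synpcc7942_1869, 2.84 ± 0.19). Other genes with nitrate in their product text rose while Synpcc7942_1489 and Synpcc7942_1490 fell: the permeases Synpcc7942_1238 (4.47 ± 0.22) and Synpcc7942_2106 (3.56 ± 0.40) and the substrate-binding gene Synpcc7942_2107 (3.77 ± 0.21). The product text of Synpcc7942_2107 names nitrate, sulfonate and bicarbonate together, so such wording does not settle what each of these transporters carries. The circadian clock genes KaiA (Synpcc7942_1218, 2.34 ± 0.24) and KaiC (Synpcc7942_1216, 1.29 ± 0.17) rose, as did the hydrogenase maturation protein HypE (Synpcc7942_1799, 2.83 ± 0.22), an ArsR family regulator (Synpcc7942_0938, 2.81 ± 0.29) and cytochrome oxidase d subunit I (Synpcc7942_1767, 2.55 ± 0.28). Control libraries A and B differed in several of these genes: without control B the changes were -8.30 for Synpcc7942_1488, -6.84 for Synpcc7942_1489, -6.27 for Synpcc7942_1490 and 5.44 for Synpcc7942_2106, and without control A it was -2.95 for the RuBisCO gene Synpcc7942_1427. Without control B the list calls ended for photosystem I and NDH-1 (adjusted p = 0.0612 each) and for phycobilisomes and ribosomal proteins (0.0536 each), the NDH-1 call also ended without NaCl day 1 A (0.0717), with the first wording of the list (0.150) and with library size alone (0.113), and the ribosomal call ended with library size alone (0.398) and without control A (0.116), NaCl day 1 A (0.0722) or B (0.0697), or NaCl day 3 A or B (0.0514 each).

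**Figure D1:**
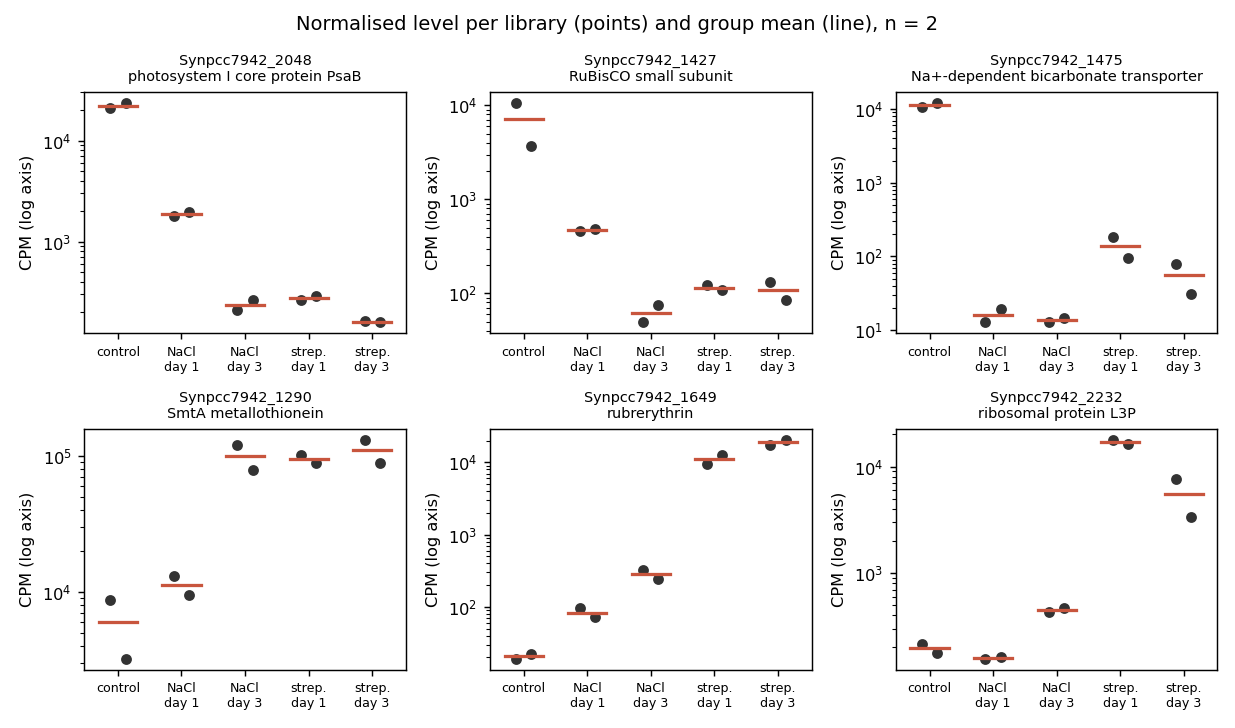
TMM-scaled CPM of 6 genes in the 5 groups on a log axis, with 1 point per library (n = 2 per group) and a line at the group mean. The bicarbonate transporter (Synpcc7942_1475) went from 11340 ± 1067 CPM in the control to 15.99 ± 4.47 on NaCl day 1 (mean ± SD), and rubrerythrin (Synpcc7942_1649) from 20.7 ± 2.32 in the control to 11158 ± 2182 on streptomycin day 1.

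On day 3 of NaCl, most genes of both photosystems, phycobilisomes, carbon fixation and the ribosome were lower than in the control, with list medians below 0 under each scaling tried. PsaB fell from 22250 ± 1887 CPM to 238 ± 40.7 CPM (-6.54 ± 0.24, adjusted p = 1.03e-09) and the RuBisCO small subunit from 7130.1 ± 4880.5 CPM to 62.5 ± 18.3 CPM (-6.83 ± 0.50). The bicarbonate transporter stayed low (-9.68 ± 0.54), and so did Synpcc7942_1488 (-9.29 ± 0.61), Synpcc7942_1489 (-8.30 ± 0.59) and Synpcc7942_1490 (-6.87 ± 0.51). SmtA metallothionein rose to 99591 ± 28922 CPM from 5981 ± 3906 CPM (4.06 ± 0.45). In all, 1971 genes changed, 974 higher and 997 lower, and 1442 changed at least 2-fold; library size alone gave 1653 higher and 466 lower.

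Of the phycobilisome list on NaCl day 3, 13 of 15 measured members fell, 1 rose and 1 did not pass the test. The median was -3.92, and 13 were lower and 1 higher when adjusted over the list alone. Camera p was 4.46e-06, with adjusted p = 0.000144, and adjusted p = 0.323 with an estimated correlation. The core component Lc 7.8 (Synpcc7942_0325, -4.97 ± 0.36) and a phycocyanin alpha subunit (Synpcc7942_1053, -4.85 ± 0.35) fell. Of the photosystem II list, 22 of 27 measured members fell, 1 rose and 4 did not pass the test. The median was -1.94, and 22 were lower and 1 higher when adjusted over the list alone. Camera p was 8.73e-06, with adjusted p = 0.000144, and adjusted p = 0.323 with an estimated correlation. The q(b) protein genes Synpcc7942_0424 (-5.70 ± 0.30) and Synpcc7942_1389 (-4.67 ± 0.41), which encode a reaction centre protein, fell. In photosystem I, 9 of 12 measured members fell, 2 rose and 1 did not pass the test. The median was -3.58, and 9 were lower and 2 higher when adjusted over the list alone. Camera p was 0.000904, with adjusted p = 0.00596, and adjusted p = 0.323 with an estimated correlation. PsaA (Synpcc7942_2049, -5.85 ± 0.25), the iron-sulfur center (Synpcc7942_0535, -5.22 ± 0.34) and PsaI (Synpcc7942_2343, -4.43 ± 0.29) fell. Of the NDH-1 list, 13 of 17 measured members fell, 0 rose and 4 did not pass the test. The median was -1.39, and 13 were lower and 0 higher when adjusted over the list alone. Camera p was 0.000134, with adjusted p = 0.0011, and adjusted p = 0.323 with an estimated correlation. Subunits 4L (Synpcc7942_1346, -5.19 ± 0.27) and 6 (Synpcc7942_1345, -5.05 ± 0.25) fell most. With library size alone the medians stayed negative, at -2.79 for phycobilisomes, -0.79 for photosystem II, -2.42 for photosystem I and -0.21 for NDH-1.

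Of the CO2 concentration and Calvin cycle list on NaCl day 3, 12 of 17 measured members fell, 4 rose and 1 did not pass the test. The median was -2.22, and 12 were lower and 4 higher when adjusted over the list alone. Camera p was 0.00577, with adjusted p = 0.0272, and adjusted p = 0.435 with an estimated correlation. The carboxysome protein CcmL (Synpcc7942_1422, -5.80 ± 0.44) fell. Among ribosomal protein genes, 40 of 53 measured members fell, 7 rose and 6 did not pass the test. The median was -1.75, and 40 were lower and 7 higher when adjusted over the list alone. Camera p was 2.17e-05, with adjusted p = 0.000239, and adjusted p = 0.374 with an estimated correlation. L12P (Synpcc7942_0631, -4.30 ± 0.25) and L10P (Synpcc7942_0632, -3.82 ± 0.25) were among the falls. Of the pili list, 11 of 16 measured members fell, 3 rose and 2 did not pass the test. The median was -2.54, and 11 were lower and 3 higher when adjusted over the list alone. Camera p was 0.00229, with adjusted p = 0.0126, and adjusted p = 0.323 with an estimated correlation. PilA-like Synpcc7942_0049 (-4.81 ± 0.25) and PilO (Synpcc7942_2451, -4.36 ± 0.26) fell. With library size alone the medians were -1.07 for the CO2 list, -0.56 for ribosomal proteins and -1.39 for pili. ATP synthase subunits C (Synpcc7942_0332, -5.09 ± 0.33) and A (Synpcc7942_0331, -4.35 ± 0.29), catalase/peroxidase HPI (Synpcc7942_1656, -6.36 ± 0.24), DnaJ-like Synpcc7942_2306 (-7.21 ± 0.22) and the sigma 54 modulation protein (Synpcc7942_2352, -6.18 ± 0.33), a ribosome-associated factor by its product text, fell too.

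Rises on NaCl day 3 were those of Beta-Ig-H3/fasciclin (Synpcc7942_1606, 6.33 ± 0.33), a conserved hypothetical protein (Synpcc7942_1801, 6.29 ± 0.35), the ArsR family regulator Synpcc7942_0938 (5.99 ± 0.30), HlyD Synpcc7942_1870 (5.78 ± 0.25) and the FUR family regulator Synpcc7942_1648 (4.52 ± 0.26). The clock genes KaiA (3.34 ± 0.25), KaiB (Synpcc7942_1217, 1.77 ± 0.23) and KaiC (1.0 ± 0.17) rose. A ThiJ family protein of the B-prefixed tags (Synpcc7942_B2643, 3.01 ± 0.25), a Txe/YoeB addiction module toxin (Synpcc7942_1207, 2.92 ± 0.20), a ComEC/Rec2-related protein (Synpcc7942_2458, 2.91 ± 0.20) and a C-terminal processing peptidase (Synpcc7942_0712, 2.91 ± 0.20) also rose. Without control B the changes were -8.29 for Synpcc7942_1488, -7.34 for Synpcc7942_1489, -5.94 for Synpcc7942_1490 and 7.65 for Synpcc7942_1801, and without control A they were -5.87 for Synpcc7942_1427, -3.78 for Synpcc7942_1389 and 4.95 for SmtA. With the first wording of the lists the CO2 and NDH-1 calls ended (adjusted p = 0.376 and 0.0548), and how reads shared by near-identical copies such as the q(b) and phycocyanin genes were assigned is not given in the sources used here.

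On day 1 of streptomycin, ribosomal protein genes were higher than in the control as a list, while photosystem I, phycobilisome and chlorophyll synthesis genes were lower, and no scaling tried turned the sign of these medians. None of these list calls held with an estimated correlation. Rubrerythrin (Synpcc7942_1649), an iron protein linked to peroxide defence, rose from 20.7 ± 2.32 CPM to 11158 ± 2182 CPM (9.06 ± 0.33, adjusted p = 5.65e-10), and an ADP-ribosylglycohydrolase-like gene (Synpcc7942_1562) rose by 8.83 ± 0.32. A conserved hypothetical protein (Synpcc7942_0180, -8.50 ± 0.32) and the chemotaxis-type genes Synpcc7942_0855 (-8.30 ± 0.35), Synpcc7942_0856 (-8.25 ± 0.33), Synpcc7942_0858 (-8.20 ± 0.24), Synpcc7942_0860 (-7.69 ± 0.32), Synpcc7942_0859 (-7.51 ± 0.27) and Synpcc7942_0857 (-5.79 ± 0.20) fell. In all, 1967 genes changed, 1001 higher and 966 lower, and 1502 changed at least 2-fold; library size alone gave 1263 higher and 745 lower.

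Of the ribosomal protein list on streptomycin day 1, 35 of 53 measured members rose, 5 fell and 13 did not pass the test. The median was 1.38, and 35 were higher and 5 lower when adjusted over the list alone. Camera p was 1.15e-05, with adjusted p = 0.000378, and adjusted p = 0.676 with an estimated correlation. L3P (Synpcc7942_2232, 6.44 ± 0.38), S14P (Synpcc7942_0446, 4.45 ± 0.24) and L19P (Synpcc7942_2541, 4.36 ± 0.25) rose most, and a possible L36 (Synpcc7942_1567, -3.95 ± 0.26) fell. These genes are short, with a median coding length of 366 bases against 777 for all genes. In 10000 random lists matched for coding length and for the mean level over all libraries, the median was 0.10 and the highest 1.23, below the list's median. The matched genes were drawn 1 by 1, so joint movement, as among the 18 ribosomal genes with consecutive tags, is not in those lists. Their spread therefore does not measure chance for this list. Among phycobilisome genes, 12 of 15 measured members fell, 1 rose and 2 did not pass the test. The median was -4.69, and 12 were lower and 1 higher when adjusted over the list alone. Camera p was 2.43e-05, with adjusted p = 0.000401, and adjusted p = 0.676 with an estimated correlation. Allophycocyanin beta (Synpcc7942_0326, -5.44 ± 0.33) and Lc 7.8 (Synpcc7942_0325, -5.22 ± 0.37) fell. In photosystem I, 10 of 12 measured members fell, 1 rose and 1 did not pass the test. The median was -3.37, and 10 were lower and 1 higher when adjusted over the list alone. Camera p was 0.00057, with adjusted p = 0.00627, and adjusted p = 0.567 with an estimated correlation. PsaB (-6.34 ± 0.24) and subunit IX (-4.46 ± 0.22) fell. Of the chlorophyll and heme synthesis list, 17 of 24 measured members fell, 2 rose and 5 did not pass the test. The median was -1.19, and 17 were lower and 2 higher when adjusted over the list alone. Camera p was 0.00165, with adjusted p = 0.0136, and adjusted p = 0.37 with an estimated correlation. The chlorophyll synthase / protochlorophyllide oxidoreductase gene (Synpcc7942_2503, -3.86 ± 0.17) and coproporphyrinogen oxidase (Synpcc7942_0674, -3.51 ± 0.20) fell.

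Of the two-component regulator list on streptomycin day 1, 24 of 43 measured members fell, 6 rose and 13 did not pass the test. The median was -1.08, and 24 were lower and 6 higher when adjusted over the list alone. Camera p was 0.00615, with adjusted p = 0.0338, and adjusted p = 0.37 with an estimated correlation. The CheY-like Synpcc7942_1693 (4.43 ± 0.27) was a member that rose. Of the pili list, 12 of 16 measured members fell, 1 rose and 3 did not pass the test. The median was -1.81, and 12 were lower and 1 higher when adjusted over the list alone. Camera p was 0.00237, with adjusted p = 0.0157, and adjusted p = 0.622 with an estimated correlation. PilC-like Synpcc7942_2069 (-5.26 ± 0.24) fell. SmtA (3.99 ± 0.44), the adjacent ArsR family regulator Synpcc7942_1291 (4.21 ± 0.26), the ArsR family Synpcc7942_0938 (5.38 ± 0.30) and the manganese transporter protein MntC (Synpcc7942_2575, 5.17 ± 0.28) rose. Thioredoxin peroxidase (Synpcc7942_2309, 6.11 ± 0.24), HypE (5.48 ± 0.25), a phosphate binding protein (Synpcc7942_2445, 5.41 ± 0.32), HlyD Synpcc7942_1870 (4.43 ± 0.24), the division inhibitor MinD gene (Synpcc7942_0220, 3.63 ± 0.26) and a high light-inducible protein (Synpcc7942_1997, 3.30 ± 0.32) also rose.

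The genes Synpcc7942_1475 (-6.35 ± 0.46), Synpcc7942_1489 (-6.16 ± 0.50) and Synpcc7942_1490 (-6.51 ± 0.50) and the RuBisCO small subunit (-5.95 ± 0.48) fell on streptomycin day 1 as well, while the CO2 and nitrogen assimilation lists were not called (adjusted p = 0.121 and 0.0959). So did a 3-oxoacyl-(acyl-carrier protein) reductase (Synpcc7942_1573, -7.07 ± 0.45), the sigma 54 modulation protein Synpcc7942_2352 (-7.03 ± 0.34), cytochrome c oxidase subunit III (-6.50 ± 0.25), DnaJ-like Synpcc7942_2306 (-6.21 ± 0.21), catalase/peroxidase HPI (-6.04 ± 0.24) and SigF (-5.03 ± 0.31). Without control A the changes were -5.0 for Synpcc7942_1427 and 4.89 for SmtA, without control B -5.20 for Synpcc7942_1489, -5.58 for Synpcc7942_1490 and 4.28 for Synpcc7942_0220, and without streptomycin day 1 B -6.77 for Synpcc7942_1489. With the first wording of the list, the chlorophyll and heme synthesis call of this day ended (adjusted p = 0.0965).

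On day 3 of streptomycin, rubrerythrin was at 18881 ± 2329 CPM (9.82 ± 0.34), and most photosystem I and phycobilisome genes were low under each scaling tried. The ArsR family regulator Synpcc7942_0938 rose by 8.08 ± 0.32, MntC by 7.08 ± 0.30 and the membrane protein MntB (Synpcc7942_2573), of the same manganese uptake system, by 4.22 ± 0.21. A conserved hypothetical protein (Synpcc7942_2307, -9.45 ± 0.26) and DnaJ-like Synpcc7942_2306 (-8.03 ± 0.23), with the tag next to it, fell. In all, 1977 genes changed, 973 higher and 1004 lower, and 1533 changed at least 2-fold; library size alone gave 1184 higher and 775 lower.

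Of the phycobilisome list on streptomycin day 3, 13 of 15 measured members fell, 1 rose and 1 did not pass the test. The median was -4.19, and 13 were lower and 1 higher when adjusted over the list alone. Camera p was 2.52e-05, with adjusted p = 0.000831, and adjusted p = 0.592 with an estimated correlation. Synpcc7942_0325 (-5.59 ± 0.38) and Synpcc7942_0326 (-5.29 ± 0.33) fell. Of the photosystem I list, 10 of 12 measured members fell, 2 rose and 0 did not pass the test. The median was -3.27, and 10 were lower and 2 higher when adjusted over the list alone. Camera p was 0.000686, with adjusted p = 0.00755, and adjusted p = 0.568 with an estimated correlation. PsaB (-7.11 ± 0.25) and the iron-sulfur center (-5.85 ± 0.35) fell. Of the chlorophyll and heme synthesis list, 17 of 24 measured members fell, 1 rose and 6 did not pass the test. The median was -1.28, and 17 were lower and 1 higher when adjusted over the list alone. Camera p was 0.000278, with adjusted p = 0.00459, and adjusted p = 0.367 with an estimated correlation. A subunit of the light-independent protochlorophyllide reductase (Synpcc7942_1420, -4.22 ± 0.24) fell. Of the NDH-1 list, 13 of 17 measured members fell, 2 rose and 2 did not pass the test. The median was -1.26, and 13 were lower and 2 higher when adjusted over the list alone. Camera p was 0.00453, with adjusted p = 0.0299, and adjusted p = 0.592 with an estimated correlation. Of the pili list, 13 of 16 measured members fell, 1 rose and 2 did not pass the test. The median was -1.44, and 13 were lower and 1 higher when adjusted over the list alone. Camera p was 0.00198, with adjusted p = 0.0163, and adjusted p = 0.568 with an estimated correlation. Of the ribosomal protein list, 28 of 53 measured members rose, 16 fell and 9 did not pass the test. The median was 0.76, and 28 were higher and 17 lower when adjusted over the list alone. Camera p was 0.0478, with adjusted p = 0.132, and adjusted p = 0.75 with an estimated correlation.

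Among ribosomal genes on streptomycin day 3, L3P (4.80 ± 0.35) and S21P (Synpcc7942_1774, 4.72 ± 0.27) rose and the possible L36 gene (-4.80 ± 0.31) fell. ADP-ribosylglycohydrolase-like Synpcc7942_1562 (7.71 ± 0.31), HypE (6.03 ± 0.25), the FUR family regulator Synpcc7942_1648 (5.68 ± 0.27), thioredoxin peroxidase (5.59 ± 0.23), MinD (5.10 ± 0.27), the ComEC/Rec2-related gene (4.68 ± 0.21), SmtA (4.21 ± 0.45) and HlyD Synpcc7942_1870 (4.19 ± 0.24) rose. The clock gene KaiC fell (-1.74 ± 0.18), while KaiA (0.19 ± 0.23, adjusted p = 0.487) and KaiB (-0.42 ± 0.25, adjusted p = 0.143) did not pass the test. Mean levels on streptomycin day 1 were 231 CPM for KaiA, 156 for KaiB and 124 for KaiC. In that order, the control had 84.7, 46.8 and 97.2 CPM, and streptomycin day 3 had 95.3, 34.2 and 29.0 CPM. The conserved hypothetical Synpcc7942_0180 (-9.16 ± 0.34), the chemotaxis-type genes Synpcc7942_0855 (-8.50 ± 0.36), Synpcc7942_0859 (-7.34 ± 0.27), Synpcc7942_0860 (-7.34 ± 0.32) and Synpcc7942_0856 (-5.99 ± 0.29), and the cytochrome c oxidase genes Synpcc7942_2604 (-7.73 ± 0.28) and Synpcc7942_2603 (-5.22 ± 0.28) fell.

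Further falls on streptomycin day 3 were those of the bicarbonate transporter (-7.70 ± 0.50), Synpcc7942_1489 (-5.21 ± 0.48), Synpcc7942_1490 (-5.67 ± 0.48), the RuBisCO small subunit (-6.04 ± 0.48), catalase/peroxidase HPI (-6.78 ± 0.25), PsbT of photosystem II (Synpcc7942_0696, -5.71 ± 0.27) and GidB (-5.41 ± 0.24). Without streptomycin day 3 A the change was 4.09 for L3P (Synpcc7942_2232) and -8.52 for Synpcc7942_1475, without control A -5.08 for Synpcc7942_1427 and 5.10 for SmtA, and without control B -4.25 for Synpcc7942_1489, -4.73 for Synpcc7942_1490 and 5.75 for Synpcc7942_0220. KaiA passed with library size alone (0.59, adjusted p = 0.0192), KaiB passed without streptomycin day 3 B (-0.73, adjusted p = 0.0474), and the chlorophyll and NDH-1 calls ended with the first wording of the lists (adjusted p = 0.0828 and 0.125).

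**Figure D2:**
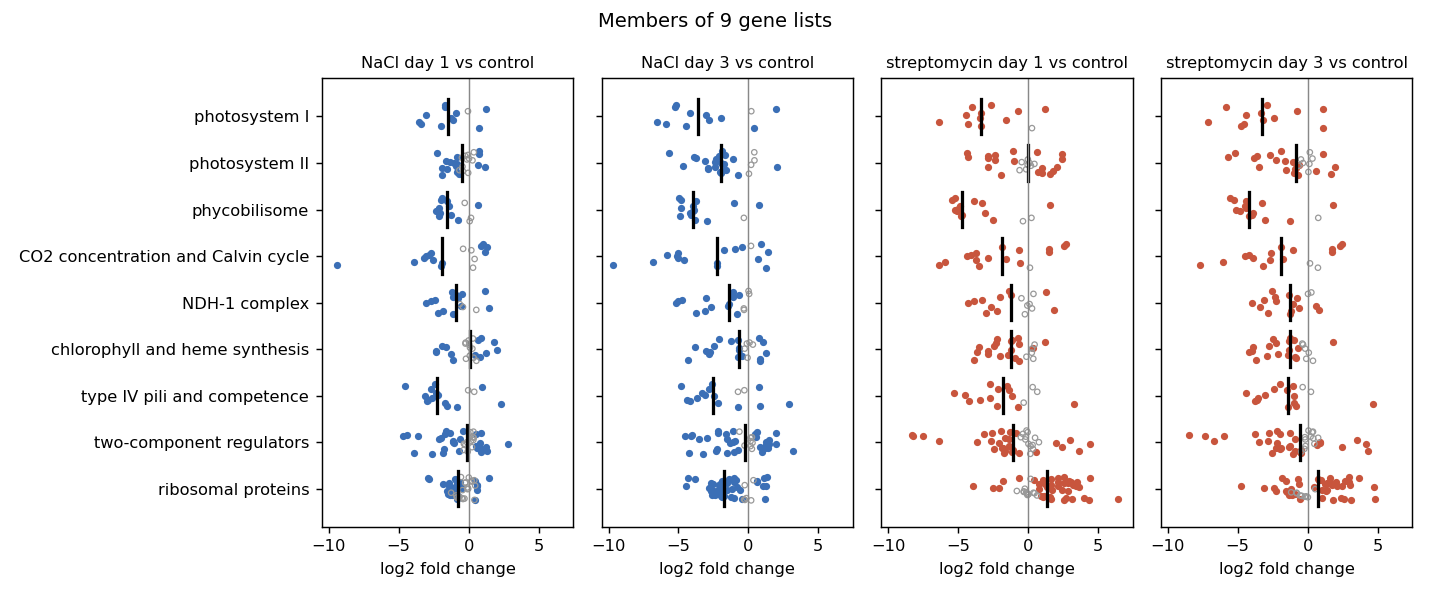
Log2 fold change against the control of each member of 9 lists in the 4 comparisons with the control, with filled points for members that passed the test, open grey points for those that did not, and a black line at the median of all members. The ribosomal protein median was -0.77 on NaCl day 1 (0.73 with library size alone) and 1.38 on streptomycin day 1, and the phycobilisome median was -3.92 on NaCl day 3 and -4.69 on streptomycin day 1.

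**Figure D3:**
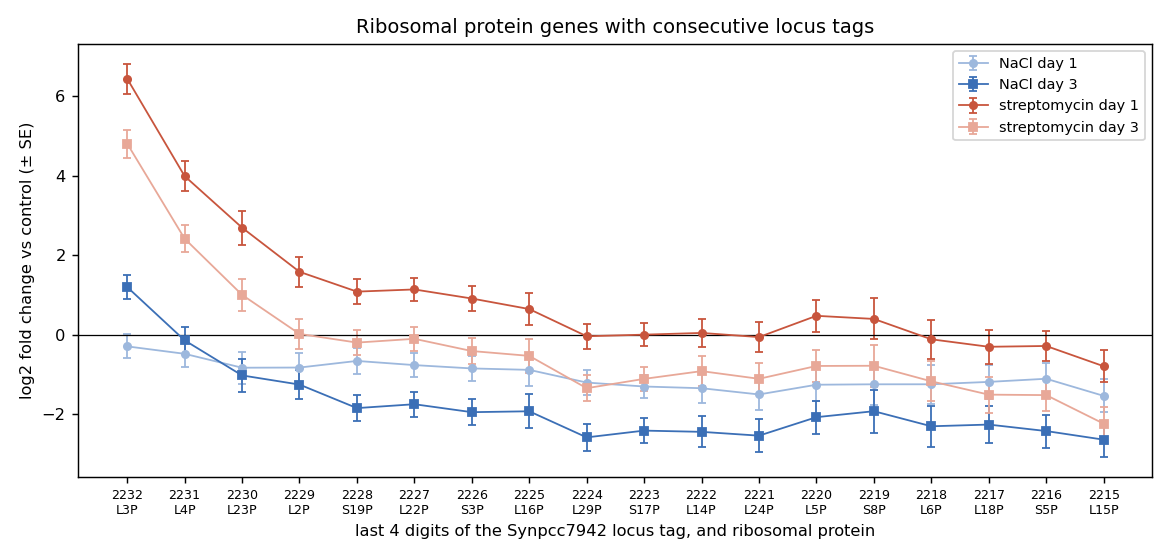
Log2 fold change ± SE against the control of 18 ribosomal protein genes with consecutive locus tags, from L3P (Synpcc7942_2232) to L15P (Synpcc7942_2215), in the 4 comparisons with the control (n = 2 libraries per group). On streptomycin day 1 the change was 6.44 for L3P and -0.80 for L15P.

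From day 1 to day 3 of NaCl, antenna, photosystem and ribosomal transcripts fell as lists. Among phycobilisome genes, 13 of 15 measured members fell, 0 rose and 2 did not pass the test. The median was -2.54, and 13 were lower and 0 higher when adjusted over the list alone. Camera p was 6.91e-08, with adjusted p = 2.28e-06, and adjusted p = 0.348 with an estimated correlation. Of the photosystem II list, 22 of 27 measured members fell, 3 rose and 2 did not pass the test. The median was -1.39, and 22 were lower and 3 higher when adjusted over the list alone. Camera p was 3.96e-07, with adjusted p = 6.54e-06, and adjusted p = 0.26 with an estimated correlation. PsbT (Synpcc7942_0696, -3.03 ± 0.24) fell. Of the photosystem I list, 8 of 12 measured members fell, 1 rose and 3 did not pass the test. The median was -2.08, and 8 were lower and 1 higher when adjusted over the list alone. Camera p was 0.000328, with adjusted p = 0.00223, and adjusted p = 0.348 with an estimated correlation. PsaB fell by 2.98 on the log2 scale (SE 0.20). Of the ribosomal protein list, 32 of 53 measured members fell, 5 rose and 16 did not pass the test. The median was -1.04, and 34 were lower and 6 higher when adjusted over the list alone. Camera p was 1.65e-05, with adjusted p = 0.000181, and adjusted p = 0.582 with an estimated correlation. Of the NDH-1 list, 12 of 17 measured members fell, 1 rose and 4 did not pass the test. The median was -1.14, and 12 were lower and 1 higher when adjusted over the list alone. Camera p was 0.000575, with adjusted p = 0.00271, and adjusted p = 0.348 with an estimated correlation. Of the CO2 list, 10 of 17 measured members fell, 0 rose and 7 did not pass the test. The median was -0.67, and 10 were lower and 0 higher when adjusted over the list alone. Camera p was 0.00224, with adjusted p = 0.00821, and adjusted p = 0.582 with an estimated correlation. CcmL was at -2.98 ± 0.42. Of the chlorophyll and heme list, 15 of 24 measured members fell, 1 rose and 8 did not pass the test. The median was -0.64, and 15 were lower and 1 higher when adjusted over the list alone. Camera p was 0.000406, with adjusted p = 0.00223, and adjusted p = 0.26 with an estimated correlation. The medians of these lists were negative under each scaling tried.

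Of the nitrogen assimilation list, 16 of 32 measured members fell from NaCl day 1 to day 3, 5 rose and 11 did not pass the test. The median was -0.65, and 17 were lower and 5 higher when adjusted over the list alone. Camera p was 0.000383, with adjusted p = 0.00223, and adjusted p = 0.348 with an estimated correlation. The permeases Synpcc7942_2106 (-5.24 ± 0.47) and Synpcc7942_1238 (-4.99 ± 0.23), which had risen on day 1, fell. Of the list of transposases, prophage and toxin-antitoxin genes, 10 of 19 measured members rose, 1 fell and 8 did not pass the test. The median was 0.77, and 10 were higher and 1 lower when adjusted over the list alone. Camera p was 0.00203, with adjusted p = 0.00821, and adjusted p = 0.26 with an estimated correlation. The toxin Txe/YoeB (Synpcc7942_1207, 2.53 ± 0.19) rose. Other rises were those of the FUR family Synpcc7942_1648 (4.43 ± 0.24), a periplasmic molybdate-binding protein (Synpcc7942_1531, 4.43 ± 0.26), the ThiJ family gene Synpcc7942_B2643 (4.0 ± 0.25), a MarR family regulator (Synpcc7942_1159, 3.27 ± 0.27), the ArsR family Synpcc7942_0938 (3.17 ± 0.24) and SmtA (3.14 ± 0.43), while a LysR family regulator (Synpcc7942_1242, -3.0 ± 0.34) fell. In all, 1415 genes changed, 686 higher and 729 lower (412 higher and 1008 lower with library size alone), and 742 changed at least 2-fold. With the first wording of the list, the transposase call ended (adjusted p = 0.120).

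From day 1 to day 3 of streptomycin, fewer genes changed: 970 in all, 510 higher and 460 lower (420 and 501 with library size alone), with 457 of at least 2-fold. Of the ribosomal protein list, 34 of 53 measured members fell, 2 rose and 17 did not pass the test. The median was -1.05, and 37 were lower and 2 higher when adjusted over the list alone. Camera p was 2.81e-10, with adjusted p = 9.28e-09, and adjusted p = 0.404 with an estimated correlation. Of the photosystem II list, 13 of 27 measured members fell, 1 rose and 13 did not pass the test. The median was -0.63, and 14 were lower and 1 higher when adjusted over the list alone. Camera p was 2.83e-06, with adjusted p = 4.66e-05, and adjusted p = 0.386 with an estimated correlation. PsbM (Synpcc7942_0699, -2.06 ± 0.25) and PsbZ (Synpcc7942_2245, -1.99 ± 0.19) fell. Of the ATP synthase list, 5 of 9 measured members fell, 0 rose and 4 did not pass the test. The median was -0.74, and 5 were lower and 0 higher when adjusted over the list alone. Camera p was 0.0033, with adjusted p = 0.0218, and adjusted p = 0.622 with an estimated correlation. Of the carotenoid synthesis list, 4 of 9 measured members fell, 0 rose and 5 did not pass the test. The median was -0.60, and 7 were lower and 0 higher when adjusted over the list alone. Camera p was 0.00775, with adjusted p = 0.0365, and adjusted p = 0.611 with an estimated correlation. Of the phosphate uptake list, 5 of 12 measured members fell, 0 rose and 7 did not pass the test. The median was -0.40, and 5 were lower and 0 higher when adjusted over the list alone. Camera p was 0.00654, with adjusted p = 0.036, and adjusted p = 0.386 with an estimated correlation. The clock genes KaiB (-2.18 ± 0.24) and KaiC (-2.10 ± 0.18), an RNA-binding protein (Synpcc7942_1999, -2.58 ± 0.33), rare lipoprotein A (Synpcc7942_1152, -2.49 ± 0.32) and DnaJ-like Synpcc7942_2306 (-1.83 ± 0.21) fell.

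Of the iron homeostasis list, 8 of 15 measured members rose from streptomycin day 1 to day 3, 1 fell and 6 did not pass the test. The median was 0.76, and 9 were higher and 1 lower when adjusted over the list alone. Camera p was 0.00217, with adjusted p = 0.0218, and adjusted p = 0.398 with an estimated correlation. The iron-stress chlorophyll-binding protein (Synpcc7942_1542) rose by 4.06 ± 0.57, the regulator of the ndhF3 operon (Synpcc7942_1310) by 3.49 ± 0.21, the ArsR family Synpcc7942_0938 by 2.71 ± 0.23 and the MarR family Synpcc7942_1159 by 2.61 ± 0.27. Synpcc7942_1542 went from 17.3 ± 0.34 CPM to 290 ± 58.8 CPM. Its control level was 160 ± 155 CPM, with the 2 libraries far apart. Some chemotaxis-type genes came up from their day 1 level: CheW Synpcc7942_0857 (2.55 ± 0.19), CheY-like Synpcc7942_0856 (2.26 ± 0.29) and CheA Synpcc7942_1014 (2.01 ± 0.18). Of the nitrogen assimilation list, 10 of 32 measured members rose, 2 fell and 20 did not pass the test. The median was 0.42, and 10 were higher and 2 lower when adjusted over the list alone. Camera p was 0.0118, with adjusted p = 0.0485, and adjusted p = 0.611 with an estimated correlation. Of the transposase list, 8 of 19 measured members rose, 0 fell and 11 did not pass the test. The median was 0.67, and 10 were higher and 0 lower when adjusted over the list alone. Camera p was 0.00306, with adjusted p = 0.0218, and adjusted p = 0.386 with an estimated correlation. With the first wording of the lists the iron, nitrogen, phosphate and transposase calls ended (adjusted p = 0.658, 0.119, 0.404 and 0.119), and the nitrogen call also ended with DESeq2 (0.0510) and without any 1 of the NaCl day 1, streptomycin day 1 or streptomycin day 3 libraries (0.0566 to 0.102). Calls also ended without streptomycin day 1 A for ATP synthase (0.0907), carotenoids (0.0776) and transposases (0.0533), without streptomycin day 3 B for ATP synthase and carotenoids (0.137 each), and without streptomycin day 1 B for phosphate (0.102), and Synpcc7942_1999 was at -3.17 without streptomycin day 3 B.

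Set directly against NaCl on day 1, streptomycin gave higher ribosomal protein transcripts and lower antenna, photosystem I and chlorophyll synthesis transcripts. Of the ribosomal protein list, 44 of 53 measured members rose, 4 fell and 5 did not pass the test. The median was 2.13 (1.12 with library size alone), and 45 were higher and 4 lower when adjusted over the list alone. Camera p was 4.3e-11, with adjusted p = 1.42e-09, and adjusted p = 0.706 with an estimated correlation. L3P was higher by 6.73 ± 0.38. Among phycobilisome genes, 13 of 15 measured members were lower, 1 higher and 1 did not pass the test. The median was -2.72, and 13 were lower and 1 higher when adjusted over the list alone. Camera p was 6.23e-05, with adjusted p = 0.000786, and adjusted p = 0.706 with an estimated correlation. In photosystem I, 10 of 12 measured members were lower, 0 higher and 2 did not pass the test. The median was -1.17, and 10 were lower and 0 higher when adjusted over the list alone. Camera p was 0.00141, with adjusted p = 0.0116, and adjusted p = 0.706 with an estimated correlation. Of the chlorophyll and heme synthesis list, 19 of 24 measured members were lower, 0 higher and 5 did not pass the test. The median was -1.26, and 19 were lower and 0 higher when adjusted over the list alone. Camera p was 7.15e-05, with adjusted p = 0.000786, and adjusted p = 0.257 with an estimated correlation. Those 3 medians were negative under each scaling tried.

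Rubrerythrin (7.07 ± 0.30), MntC (4.74 ± 0.26), a sigma-24 factor (Synpcc7942_2004, 4.42 ± 0.27), a LysM peptidoglycan-binding protein (Synpcc7942_0598, 4.09 ± 0.20), Hsp20 (Synpcc7942_2401, 4.0 ± 0.26) and CheW Synpcc7942_1016 (3.89 ± 0.26) were higher with streptomycin than with NaCl on day 1. The nitrate transport permease Synpcc7942_2106 (-6.56 ± 0.53, or -7.46 without streptomycin day 1 B), a glycosyltransferase (Synpcc7942_1902, -5.53 ± 0.25), the LysR family Synpcc7942_1242 (-4.33 ± 0.38) and the chemotaxis-type Synpcc7942_0860 (-4.15 ± 0.29), Synpcc7942_0855 (-3.90 ± 0.29), Synpcc7942_0859 (-3.87 ± 0.24) and Synpcc7942_0856 (-3.54 ± 0.28) were lower. In all, 1923 genes differed, 963 higher and 960 lower (391 and 1607 with library size alone), 1302 of them at least 2-fold.

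On day 3 the ribosomal protein list was higher with streptomycin than with NaCl, where 43 of 53 measured members were higher, 0 lower and 10 did not pass the test. The median was 1.65 (0.87 with library size alone), and 43 were higher and 0 lower when adjusted over the list alone. Camera p was 3.08e-10, with adjusted p = 1.02e-08, and adjusted p = 0.803 with an estimated correlation. No other list was called on that day. CheW Synpcc7942_1016 (5.81 ± 0.29), TatA (Synpcc7942_0226, 4.31 ± 0.28), MntC (4.28 ± 0.25), the nickel insertion protein HypA (Synpcc7942_2553, 4.20 ± 0.30) and the sigma-24 factor Synpcc7942_2004 (4.12 ± 0.28) were higher, as were the conserved hypothetical Synpcc7942_1890 (8.05 ± 0.38) and the hypothetical Synpcc7942_0522 (7.04 ± 0.24). A diguanylate cyclase-type response regulator (Synpcc7942_1355, -5.76 ± 0.26), cytochrome c oxidase subunit III (-5.29 ± 0.26), Synpcc7942_0855 (-4.50 ± 0.31), ThiJ family Synpcc7942_B2643 (-3.25 ± 0.26), Synpcc7942_0859 (-3.22 ± 0.25), Synpcc7942_0860 (-3.22 ± 0.30) and KaiA (-3.16 ± 0.24) were lower. In all, 1858 genes differed, 953 higher and 905 lower (549 and 1404 with library size alone), 1370 of them at least 2-fold.

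The responses to NaCl and streptomycin shared many genes, counted here on the TMM scale. On day 1, 504 genes rose and 565 fell in both, where independent responses of the same size would share 318 and 306, and 258 genes went opposite ways. On day 3, 575 rose and 643 fell in both (357 and 377 if independent), and 316 went opposite ways. Across genes, which are not independent replicates, the log2 fold changes of the stresses had a correlation of 0.653 and a covariance of 2.05 on day 1, and 0.665 and 2.83 on day 3. In 30 simulated data sets with every group unchanged, the same 2 control libraries in both comparisons gave a covariance of 0.0370 on average and 0.0413 at most for day 1 (0.0368 and 0.0427 for day 3), a mean correlation of 0.504 (0.441), and 0 genes called the same way in both. Of the genes that went the same way in both stresses, 701 on day 1 and 752 on day 3 also differed between the stresses in the direct comparison, as did all 258 and all 316 that went opposite ways. The 2 control libraries could not be split between the comparisons. In all 4 comparisons with the control, 373 genes were higher and 449 lower.

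**Figure D4:**
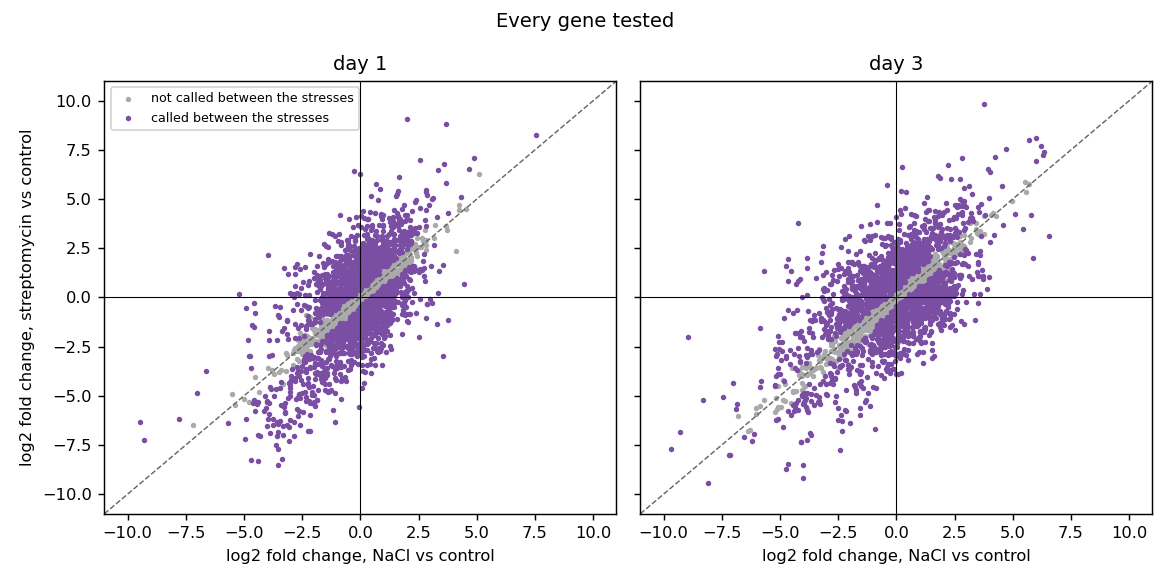
Log2 fold change of each gene against the control with NaCl (horizontal axis) and with streptomycin (vertical axis) on day 1 and on day 3, with genes that differed between the stresses in purple and the line of equal change dashed. The correlation across genes was 0.653 on day 1 and 0.665 on day 3. Simulated unchanged groups, whose fold changes were small, gave 0.504 and 0.441 on average through the shared control libraries. These correlations do not measure how much of the likeness the shared libraries give. The covariance was 2.05 on day 1 and 2.83 on day 3, against simulated means of 0.0370 and 0.0368.

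The change from day 1 to day 3 itself differed between the stresses for 993 genes, 514 with a higher and 479 with a lower change under streptomycin (647 and 304 with library size alone), and 766 differed at least 2-fold. A higher change is not a higher level, since the levels of many genes already differed between the stresses on day 1. Of the phycobilisome list, 13 of 15 measured members had a higher change under streptomycin, 0 a lower one and 2 did not pass the test. The median was 2.14, and 13 were higher and 0 lower when adjusted over the list alone. Camera p was 7.2e-08, with adjusted p = 2.38e-06, and adjusted p = 0.636 with an estimated correlation. Of the nitrogen assimilation list, 19 of 32 measured members had a higher change under streptomycin, 3 a lower one and 10 did not pass the test. The median was 1.45, and 20 were higher and 3 lower when adjusted over the list alone. Camera p was 1.4e-05, with adjusted p = 0.00023, and adjusted p = 0.636 with an estimated correlation. Of the photosystem I list, 7 of 12 measured members had a higher change under streptomycin, 1 a lower one and 4 did not pass the test. The median was 1.40, and 8 were higher and 1 lower when adjusted over the list alone. Camera p was 0.00162, with adjusted p = 0.0178, and adjusted p = 0.636 with an estimated correlation. Of the CO2 list, 9 of 17 measured members had a higher change under streptomycin, 0 a lower one and 8 did not pass the test. The median was 0.86, and 9 were higher and 0 lower when adjusted over the list alone. Camera p was 0.0039, with adjusted p = 0.0321, and adjusted p = 0.708 with an estimated correlation. That call ended with the first wording of the list (adjusted p = 0.119) and without NaCl day 3 A (0.0554) or streptomycin day 3 A (0.0656).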

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

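The test of time in culture below was chosen only after the result was seen; the test of the shared control libraries was not.

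The change from day 1 to day 3 differed between the stresses, by the test of the difference itself, for each gene and list given here, as streptomycin minus NaCl in log2 units. Nitrate transport permeases stood out: Synpcc7942_2106 differed by 6.91 ± 1.31 (NaCl -5.24; streptomycin 1.68, adjusted p = 0.229) and Synpcc7942_1238 by 6.04 ± 0.33 (NaCl -4.99, streptomycin 1.05). Synpcc7942_2106 was at 0.35 CPM on streptomycin day 1, 1.07 on streptomycin day 3 and 0.95 on NaCl day 3. A floor of 3 counts was up to 1.08 CPM without TMM scaling, so the size of its difference is uncertain. The difference of Synpcc7942_2106 lost its call without streptomycin day 3 B (5.46, adjusted p = 0.149) and was 7.82 without streptomycin day 1 B. The LysR family regulator Synpcc7942_1242 differed by 3.03 ± 0.81 (NaCl -3.0, streptomycin 0.03), but by 1.48 (adjusted p = 0.372) without streptomycin day 3 A and 3.97 without streptomycin day 3 B. Synpcc7942_1242 was also low with streptomycin, at 1.68 CPM on day 1 and 1.94 ± 1.94 CPM on day 3. The CheA histidine kinase Synpcc7942_1014 differed by 3.03 ± 0.26, falling with NaCl (-1.02) and rising with streptomycin (2.01). The carboxysome protein CcmL (Synpcc7942_1422) differed by 2.85 ± 0.58 (NaCl -2.98; streptomycin -0.14, adjusted p = 0.811). The NdhF3 subunit of NDH-1 (Synpcc7942_2091) differed by 2.32 ± 0.38 (NaCl -1.31, streptomycin 1.0), and PsaB (Synpcc7942_2048) by 2.21 ± 0.27 (NaCl -2.98, streptomycin -0.77). The mean level of PsaB was still lower with streptomycin, at 275 CPM on day 1 and 161 CPM on day 3. With NaCl it was 1878 CPM on day 1 and 238 CPM on day 3.

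Other genes had a lower change with streptomycin than with NaCl. The phosphate binding protein Synpcc7942_2445 differed by -4.02 ± 0.38 (NaCl 2.0, streptomycin -2.02), or -4.61 without streptomycin day 3 B, and 6-phosphogluconolactonase (Synpcc7942_0529) by -3.92 ± 0.27 (NaCl 2.96, streptomycin -0.96). The ThiJ family gene Synpcc7942_B2643 differed by -3.38 ± 0.40 (NaCl 4.0, streptomycin 0.62), and NblA (Synpcc7942_2127), a protein needed for the breakdown of phycobilisomes, by -3.07 ± 0.35 (NaCl 2.36, streptomycin -0.71). The clock protein KaiB (Synpcc7942_1217) differed by -3.02 ± 0.33 (NaCl 0.84, streptomycin -2.18), SmtA (Synpcc7942_1290) by -2.93 ± 0.57 (NaCl 3.14, streptomycin 0.22) and DnaJ-like Synpcc7942_0812 by -2.92 ± 0.28 (NaCl 2.35, streptomycin -0.57). As lists, the median difference in change, which is not one in level, was 2.14 for phycobilisomes, 1.45 for nitrogen assimilation, 1.40 for photosystem I and 0.86 for CO2 concentration and the Calvin cycle, each positive under every scaling tried. None of these list calls held with an estimated correlation (adjusted p = 0.636 for each of the first 3 and 0.708 for the CO2 list). The CO2 call also ended without NaCl day 3 A (0.0554) or streptomycin day 3 A (0.0656) and with the first wording of the list (0.119).

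Against the control and on the TMM scale, 258 genes on day 1 and 316 on day 3 were called in opposite directions by NaCl and streptomycin. All of them also differed in the direct comparison, which opposite calls all but fix in advance. Most of the shared genes moved the same way. Chance values of the shared control libraries, as far as the spread between A and B measures them, are argued against as the source of this likeness. The covariance of the fold changes on day 1 was 2.01 above the mean of the simulated unchanged groups. If A and B are technical repeats, a chance state of the day 0 culture is not in those simulations. Of the 822 genes called the same way in all 4 comparisons with the control, 83.8% differed between the stresses on day 1 or day 3, as did 86.4% of all genes, and such a difference leaves open what the stresses share. For what these 822 genes share, time in culture and a response to both stresses cannot be told apart, because every control library is from day 0. A general response to either stress may underlie part of the likeness, and stays a hypothesis from these same data, with no control of the same age to test it.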

How the results depend on the processing

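The lists as first worded and camera with library size alone were chosen after seeing the data. With library size alone the genes higher and lower were 2000 and 241 on NaCl day 1, 1653 and 466 on NaCl day 3, 391 and 1607 between the stresses on day 1, and 549 and 1404 on day 3, with 412 higher from NaCl day 1 to day 3 and 304 lower in the difference of the time changes; this setting leaves the shift of the median gene in the fold changes. It also reversed glycogen phosphorylase (Synpcc7942_0244) on NaCl day 1, to 0.65 (adjusted p = 0.00333), and on NaCl day 3, to 0.55, and on NaCl day 1 glucose-1-phosphate adenylyltransferase (Synpcc7942_0603), to 0.68 (adjusted p = 0.0128), and the SigF gene Synpcc7942_1784, to 0.17 (adjusted p = 0.448). With an estimated correlation 0 lists were called, against 23 in the 4 comparisons with the control; the cause was not tested. When each library was left out in turn, the lone library left in a group being assumed to vary like the other groups, the genes higher from NaCl day 1 to day 3 were 456 to 727, those changed from streptomycin day 1 to day 3 were 629 to 1002, and those lower were 287 to 477; fewer libraries then set the spread. All other counts of changed, higher or lower genes stayed within 1.5 times, over the settings run, and the named genes kept their direction and call with DESeq2, limma-voom, RLE or upper-quartile factors and the other filters, except that the MIP family channel (Synpcc7942_1571) was called with upper-quartile factors on NaCl day 1 (1.01, adjusted p = 0.0214) and streptomycin day 1 (0.98, adjusted p = 0.0309). With the letter as a replicate block, 1770 genes changed on NaCl day 1, 2015 on NaCl day 3, 2027 on streptomycin day 1 and 2016 on streptomycin day 3, and no named gene or list changed its call; the differences between A and B had correlations of -0.03 to 0.44 across genes over the 10 pairs of groups. The alternative that leaves out ribosomal and transfer RNA was not run, since the tables hold none. Depth limits the genes with few counts: a floor of 3 counts was up to 1.08 CPM without TMM scaling, and Synpcc7942_2106 had only 4 counts in its lowest group.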

Other observations

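The tests of the total counts and of a gradient absent with NaCl were chosen only after the result was seen; the other tests here were not.

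Values in this paragraph and the next are in the order NaCl day 1, NaCl day 3, streptomycin day 1 and streptomycin day 3 against the control, unless a comparison is named. Of the 7 members of the list of compatible solutes and glycogen, 4, 5, 6 and 6 were lower and 1 was higher each time, and the list was not called (adjusted p = 0.562, 0.278, 0.121 and 0.0952). Glycogen debranching enzyme (Synpcc7942_1575) fell in all 4 (-2.38 ± 0.30, -1.97 ± 0.33, -1.90 ± 0.32 and -1.50 ± 0.34). Glucose-1-phosphate adenylyltransferase (Synpcc7942_0603), which makes the glucosyl donor of glycogen synthesis, was at -0.79 ± 0.19, -2.29 ± 0.20, -2.14 ± 0.20 and -2.79 ± 0.21, and glycogen phosphorylase (Synpcc7942_0244) at -0.83 ± 0.17, -0.61 ± 0.17, -2.56 ± 0.18 and -2.46 ± 0.18. With library size alone, Synpcc7942_0603 turned to 0.68 on NaCl day 1 and Synpcc7942_0244 to 0.65 on NaCl day 1 and 0.55 on NaCl day 3, where Synpcc7942_0244 also lost its call without NaCl day 3 B (-0.52, adjusted p = 0.0591). A putative neutral invertase (Synpcc7942_0397), an enzyme that splits sucrose, rose in all 4 (1.30 ± 0.19, 1.75 ± 0.19, 0.75 ± 0.19 and 0.72 ± 0.20). Of a putative multicomponent Na+:H+ antiporter, with locus tags near that of the bicarbonate transporter, Synpcc7942_1473 (-3.27 ± 0.22, -2.58 ± 0.21, -5.59 ± 0.24 and -5.02 ± 0.24) and Synpcc7942_1468 (-2.48 ± 0.22, -2.49 ± 0.23, -5.80 ± 0.28 and -5.62 ± 0.29) fell in all 4. The single-gene Na+/H+ antiporters Synpcc7942_2394 on NaCl day 1 (0.79 ± 0.17) and Synpcc7942_1264 on streptomycin day 1 (1.16 ± 0.17) rose slightly. A MIP family channel (Synpcc7942_1571) rose on NaCl day 3 (2.50 ± 0.33) and did not pass the test in the others (0.82 ± 0.35, 0.63 ± 0.38 and 0.18 ± 0.45). It was called on NaCl day 1 and streptomycin day 1 with library size alone (2.27 and 1.07, adjusted p = 2.71e-05 and 0.0196) and with upper-quartile factors (1.01 and 0.98). The large conductance mechanosensitive channel (Synpcc7942_1991) fell on NaCl day 1 (-1.52 ± 0.25, or -0.06 with library size alone) and NaCl day 3 (-2.75 ± 0.30), rose on streptomycin day 1 (1.12 ± 0.24) and did not pass on streptomycin day 3 (-0.30 ± 0.26, adjusted p = 0.305), where it was called without streptomycin day 3 B (-0.71, adjusted p = 0.0491).

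Among sigma factors, which direct RNA polymerase to promoters, SigB (Synpcc7942_1746) rose in all but NaCl day 1, where it was called only with library size alone (1.65, adjusted p = 1.2e-06; TMM values 0.16 ± 0.19, 0.93 ± 0.19, 1.89 ± 0.19 and 2.91 ± 0.20). SigC (Synpcc7942_1849) fell in all 4 (-1.93 ± 0.26, -4.04 ± 0.29, -3.87 ± 0.29 and -4.36 ± 0.30), and on NaCl day 1 it was at -0.47 (adjusted p = 0.113) with library size alone. The SigF genes Synpcc7942_1510 (-4.11 ± 0.29, -3.96 ± 0.29, -5.03 ± 0.31 and -4.55 ± 0.32) and Synpcc7942_1784 (-1.32 ± 0.23, -3.32 ± 0.25, -4.77 ± 0.27 and -5.09 ± 0.28) fell in all 4, and library size alone turned Synpcc7942_1784 on NaCl day 1 to 0.17 (adjusted p = 0.448). Of the 5 FUR family genes, a family that includes repressors of iron uptake, Synpcc7942_0817 rose with NaCl (3.06 ± 0.22 and 3.38 ± 0.22), did not pass on streptomycin day 1 (-0.27 ± 0.22, adjusted p = 0.288) and fell on streptomycin day 3 (-1.15 ± 0.26). Another, Synpcc7942_1648, did not pass on NaCl day 1 (0.09 ± 0.25, adjusted p = 0.763; 1.57 and called with library size alone) and rose in the other 3 (4.52 ± 0.26, 4.38 ± 0.25 and 5.68 ± 0.27). Flavodoxin (Synpcc7942_1541), which replaces ferredoxin when iron is short, fell in all 4 (-2.19 ± 0.31, -3.23 ± 0.34, -3.14 ± 0.34 and -1.07 ± 0.31), and without control B these changes were -1.44, -2.48, -2.39 and -0.31, the last with adjusted p = 0.228. Its call also ended with library size alone on NaCl day 1 (-0.75, adjusted p = 0.0616) and streptomycin day 3 (-0.72, adjusted p = 0.0858), and on streptomycin day 3 without streptomycin day 3 B (-0.88, adjusted p = 0.0573). An iron transport substrate-binding protein (Synpcc7942_1409) rose on streptomycin day 3 (2.46 ± 0.24). A multidrug efflux transporter (Synpcc7942_1938) rose on streptomycin day 1 (3.21 ± 0.38), streptomycin day 3 (4.36 ± 0.36) and NaCl day 3 (1.27 ± 0.45), where the call ended without either control or either NaCl day 3 library (adjusted p = 0.0535 to 0.0857), and it did not pass on NaCl day 1 (0.28 ± 0.46, adjusted p = 0.616), where it was called with library size alone (1.71, adjusted p = 0.00272). HlyD Synpcc7942_0553 (2.33 ± 0.20, 2.96 ± 0.20, 2.73 ± 0.20 and 3.52 ± 0.21) and an Amt1-like ammonium transporter (Synpcc7942_0965, 2.29 ± 0.19, 2.14 ± 0.19, 1.58 ± 0.18 and 2.39 ± 0.19) rose in all 4.

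At like totals, the median gene had fewer counts in the control than on NaCl day 1, and scaling by library size alone put the median gene at 1.50 above the control. The test chosen first, thinning the libraries to equal totals (1.52), was replaced, because scaling by the total all but fixes its outcome. A difference in total counts is argued against by the totals, 4386954 and 8417282 in the control and 4456000 and 8364833 on NaCl day 1. Between libraries of a group the TMM factors differed by 0.201 at most in log2 units while the totals differed by up to 0.940, against 1.48 between NaCl day 1 and control factors. These factors are taken after scaling by the total, so their test adds little. A few genes taking most of the counts may be part of it, since the 50 genes with the highest share held 56.9% and 53.8% of control counts and 34.4% and 33.8% of NaCl day 1 counts; without them the median was 0.955, 63.7% of its value, which leaves this open. No biological explanation was tested, and total messenger RNA per cell was not analysed here.

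In the run of 18 ribosomal protein genes, the log2 fold change fell along the locus tags from L3P (Synpcc7942_2232) to L15P (Synpcc7942_2215), mostly up to L29P (Synpcc7942_2224). Spearman's rho with the tag number, across genes that are not independent replicates, was 0.785 on NaCl day 1, 0.781 on NaCl day 3, 0.938 on streptomycin day 1 and 0.915 on streptomycin day 3. Coding length (rho 0.251) and the level in the control (rho -0.288) did not follow the gradient of streptomycin day 1. These comparisons share the control libraries, so a gradient in the control enters all 4; in comparisons without them rho was 0.901 for streptomycin against NaCl on day 1 and 0.874 on day 3, 0.507 from NaCl day 1 to day 3 (0.531 in replicate A and 0.467 in B) and -0.577 from streptomycin day 1 to day 3 (-0.346 and -0.362). An effect that streptomycin has and NaCl has not was first argued against by the 0.781 of NaCl day 3. That test was replaced after its result, because the controls are shared. The 0.507 of NaCl that replaced it lies between the bounds set and does not decide. Such an effect could not give a gradient in that comparison, which holds no streptomycin library. As a source of the gradient with streptomycin it stays open, as do RNA quality and read positions, which were not analysed here.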
